A study of Arabidopsis thaliana with 21 samples.

How the data were processed

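The authors deposited a table of counts per gene and a table of FPKM values for the 21 libraries. Per the labels, RNA was extracted from roots with TRIzol and treated with DNase, and poly-A libraries were made with a TruSeq RNA kit. The labels give the tissue as roots and the cell type as root meristem cell. Per the submitters' processing notes, STAR 2.7.8a, StringTie 2.1.3 and HTSeq were used, with no version for HTSeq. The genome build and whether reads were counted by strand are not given in the sources used here. Of the 32833 genes in the table, 32548 (99.1%) had a locus in the TAIR10.1 reference, and 32532 of these had the same start and end there. Coordinates are given on that reference. Every one of the 461492 deposited FPKM values above 0 was 10 times the FPKM recomputed from the counts, so the FPKM values were divided by 10 before use.

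The deposited counts were analysed with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and edgeR's filter on low counts by group, which left 19938 genes. All 21 libraries entered 1 fit with 7 group means and 14 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with calls at an adjusted p under 0.05. The average of the 3 AtCEP5 effects and the differences between times were contrasts of the same fit. Fold changes are on the log2 scale, first group minus second, with their standard error (SE). Rose and fell, like raised and lowered, mean higher and lower in the first group than in the second. For AtCEP5 against mock they do not give the change since before treatment. CPM are counts scaled to library size with TMM factors. A fold against a group with 0 reads is given as a bound computed with 3 counts per library at the mean depth of both groups, and a fold against a group with 1 to 3 reads is given as the ratio of reads scaled for depth with its counting interval. Averages over times are fitted values, also where 1 group had few reads at a time, as MIOX4, TPS13, DIN11 and LOG5 with mock. Such intervals and bounds cover counting error only.

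For the gene lists, camera from limma 3.58.1 was run on log2 CPM (prior count 2) with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the lists within a comparison. The 27 lists cover auxin response, auxin transport, synthesis and perception, cytokinin response, cytokinin metabolism and signalling, the CEP pathway, nitrogen, cell division, cell cycle inhibitors, root meristem, ribosome biogenesis, root cap, endodermis, suberin, root hair, xylem, phloem, photosynthesis as a mark of shoot tissue, immunity and wounding, jasmonate, abscisic acid and drought, ethylene, the circadian clock, iron, phosphate, sulfur, cell expansion and heat. Of 189 list tests over 7 comparisons 72 passed with the preset correlation, and 62 of these did not with an estimated one. The tests, the lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where stated.

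The named genes of each comparison of AtCEP5 with mock were the 8 with the largest positive and the 8 with the largest negative log2 fold change among those that passed, had a mean of at least 1 CPM and a symbol, and had all 3 libraries of 1 group above all 3 of the other. To these were added up to 3 passing members with the smallest adjusted p of each of 8 lists (both auxin lists, both cytokinin lists, CEP pathway, nitrogen, cell division and root meristem), and ARR5, IAA19, CEPD1, CEPD2, CEPR1, CEPR2, CEP5 and NRT2.1 whatever their p. For the average the direction also had to be the same at all 3 times. For mock against before treatment 4 genes per direction and the clock list were taken, for the differences between times up to 5 genes, and from any other list that passed its test up to 3 members. Further list members given as examples were chosen after their values were seen. Of the 98 genes named by the rule 16 overlap another gene, 14 of them on the opposite strand, so the counts of these 14 are uncertain where reads were not counted by strand. These 14 include ASN1, GAT1_2.1, BCAT-2, CWINV5, CYCD1;1, CEPR2, TPS13, NRT1.8, UGT84A1 and NRT1.5. HIPP21 and CYCD3;1 overlap a gene on the same strand, which counting by strand would not resolve.

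The replicate number was tested as a pairing by correlating residuals across genes. At 6 h AtCEP5 and mock libraries of the same number had correlations of 0.182, 0.117 and 0.241, all above the set minimum of 0.1. Each library also correlated best with its own number, which met the rule set for pairing. At 12 h (0.0301, −0.0495 and 0.0296) and 24 h (−0.194, 0.0919 and −0.14) the libraries did not meet it. With 3 libraries per group a match at 1 time can arise by chance, so shared batches are not established. The main fit treats the libraries as unpaired. Alternatives used DESeq2 1.42.0, DESeq2's size factors (RLE), other filters, a replicate block, limma on log2 FPKM, the 6 libraries of a comparison alone, and each library left out in turn. A simulation redrew the counts gene by gene from means and spreads of these data, with 200 changed genes. At 6 h edgeR recovered 63% of genes changed 2-fold and 96% of those changed 4-fold, with 1.9% false calls. In the average it recovered 89% and 99%, with 5.5% false calls. False calls were 2.4% and 8.4% in limma and 10.4% and 14.3% in DESeq2. Genes were drawn independently and few were changed, unlike in these data, so these shares may not carry over.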

Results

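The data collected were RNA-seq libraries from Arabidopsis thaliana roots, sampled before treatment (0 h) and 6, 12 and 24 h after mock treatment or treatment with AtCEP5, a small secreted signalling peptide of the C-TERMINALLY ENCODED PEPTIDE (CEP) family. Each of the 7 groups held 3 libraries, 21 in all. Total counts ranged from 10334319 in mock 6 h replicate 2 to 14345476 in the second library taken before treatment. Ribosomal RNA genes took 2.196% of the counts in mock 6 h replicate 2 and 1.96% in AtCEP5 12 h replicate 3, against 0.270–0.601% in the other libraries. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

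On the first principal component of log2 CPM (32.5% of the variance), the libraries taken before treatment (mean −47.7) and the mock libraries (means 29.5, 25.7 and 18.1 at 6, 12 and 24 h) lay at opposite ends. The AtCEP5 libraries lay between them, with means of −3.48, −12.0 and −10.1. On the second component (21.7%) the AtCEP5 groups had means of 13.3, 25.2 and 25.5. The mock groups had −20.2, −7.08 and −5.06 there, and the group taken before treatment had −31.7.

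**Figure D1:**
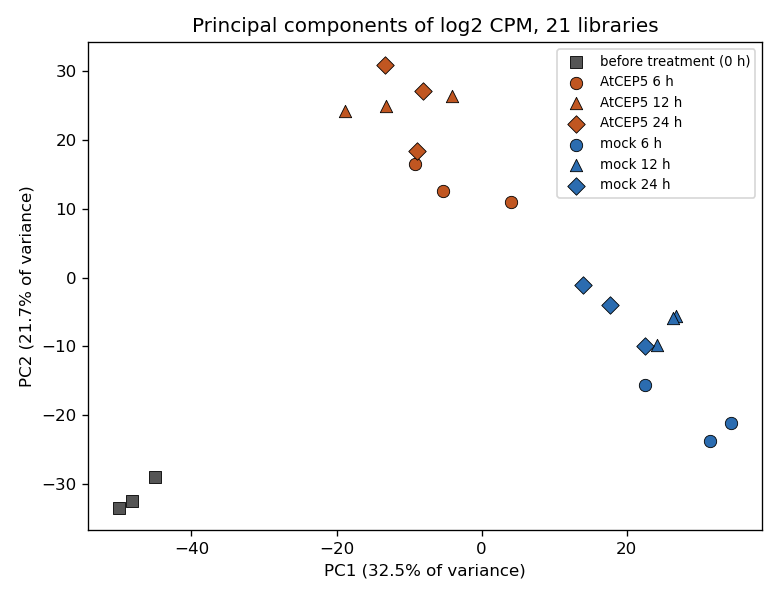
Principal components of log2 CPM over the 2000 most variable genes, with PC1 on the x axis (32.5% of the variance), PC2 on the y axis (21.7%), 1 point per library and 3 libraries per group. The 9 AtCEP5 libraries lie above the 9 mock libraries on PC2, and the 3 libraries from before treatment lie apart at the lower left, at a mean PC1 of −47.7.

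The comparison of AtCEP5 with mock at each time addresses which root transcripts change with the peptide, with auxin and cytokinin genes as the study's stated subject. ASN1, the dark-inducible asparagine synthetase (AT3G47340, chromosome 3, 17437840–17441431), stood after 6 h at 32.4 ± 15.1 CPM with AtCEP5 against 0.999 ± 0.742 CPM with mock (mean ± SD, n = 3 each). Its log2 fold change was 4.95 ± 0.63 (± SE) with an adjusted p of 1.72e-05. MIOX4, a myo-inositol oxygenase (AT4G26260, chromosome 4, 13297695–13300444), had 363 reads in the 3 AtCEP5 libraries and 3 in the 3 mock libraries, a ratio of 104 after scaling for depth, with a counting interval of 35.4–508. SEN1, a senescence- and darkness-associated gene (log2 3.84 ± 0.68), BCAT-2, a branched-chain amino acid aminotransferase (3.62 ± 0.53), and GAT1_2.1, a class I glutamine amidotransferase-like gene (3.88 ± 0.61), also rose. The sucrose exporter SWEET12 (3.12 ± 0.63), the trehalose phosphate synthase family gene TPS11 (3.09 ± 0.37) and ATCTH (3.12 ± 0.57) were higher than with mock as well. SWEET12 had 55.4–116 CPM before treatment, 2.55–7.37 with AtCEP5 and 0–1.21 with mock at 6 h, so it fell less than in mock. SEN1, BCAT-2 and ATCTH with AtCEP5 also lay below their level before treatment. ASN1, MIOX4 and GAT1_2.1 lay above it, and TPS11 overlapped it. ATC, a relative of the flowering repressor TFL1 (AT2G27550, chromosome 2, 11773187–11774746), fell from 94.2 ± 13.4 CPM with mock to 2.73 ± 1.05 CPM with AtCEP5 (log2 −5.11 ± 0.29, adjusted p = 3.61e-10). Other genes lower than with mock were the sulfate transporter SULTR1;3 (−4.33 ± 0.49), the sugar exporter SWEET14 (−3.96 ± 0.55) and the cell wall invertase CWINV5 (−3.07 ± 0.54). SULTR1;3 had 0–0.472 CPM before treatment, 0.217–0.468 with AtCEP5 and 6.28–7.68 with mock, so it had risen in mock. HIPP21 (−2.92 ± 0.38) and LSU2, a gene of the sulfur deficiency response (−2.87 ± 0.30), fell too. For each of these genes all 3 AtCEP5 libraries lay on the same side of all 3 mock libraries. Among the lowered genes, BXL3 (log2 −3.87 ± 1.01, adjusted p = 0.0141) rested on mock 6 h replicate 2. Without that library its log2 fold change was −0.18 (adjusted p = 0.926), and without any 1 AtCEP5 library its adjusted p was 0.0506–0.0699. BBX30, a B-box gene (−2.97 ± 0.83, adjusted p = 0.0221), had adjusted p values of 0.066–0.0801 without any 1 of the AtCEP5 libraries or of mock replicates 1 and 2.

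The peptide's own gene fell at 6 h. CEP5 (AT5G66815, chromosome 5, 26677365–26678002) stood at 0.998 ± 0.491 CPM with AtCEP5 and 17.63 ± 1.44 CPM with mock (log2 −4.15 ± 0.34, adjusted p = 8.99e-08), and CEP4 had 3 reads against 143, with a counting interval of 18.6–272 for the ratio (from 11.9 without AtCEP5 replicate 3). The other 4 tested members of the CEP pathway list did not pass, among them the receptor genes CEPR1 (0.25 ± 0.21, adjusted p = 0.506) and CEPR2 (−0.13 ± 0.23, 0.785) and the shoot-to-root signal gene CEPD1 (0.48 ± 0.27, 0.276). The list's median was 0.06 and its mean −1.46, so they differ in sign, and camera gave an adjusted p of 0.0675.

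Auxin genes moved in both directions at 6 h. Of 40 tested auxin response genes 2 rose and 3 fell, or 4 and 7 adjusted over the list alone. GH3.2, which conjugates auxin to amino acids, rose (1.24 ± 0.18, adjusted p = 7.18e-05). IAA14, a repressor of auxin signalling in lateral root initiation (AT4G14550, chromosome 4, 8347822–8350263), fell (−1.20 ± 0.18, adjusted p = 8.09e-05). IAA2 rose by 0.52 ± 0.14 with an adjusted p of 0.0158, which became 0.0629–0.0804 without AtCEP5 replicate 2, AtCEP5 replicate 3 or mock replicate 1. IAA19 had a log2 fold change of −0.57 ± 0.19 with an adjusted p of 0.0517, and passed with DESeq2's size factors (0.0469) and with DESeq2 (0.0443), within a range of 0.0443–0.19 over the alternatives run. The list as a whole did not pass camera (adjusted p = 0.17). Of 33 genes of auxin transport, synthesis and perception, 3 fell, including the synthesis genes CYP79B2 (−0.79 ± 0.15) and YUC9 (−1.35 ± 0.30), and 1 rose, the auxin receptor TIR1 (0.50 ± 0.14). The adjusted p of TIR1 was 0.0734–0.107 without AtCEP5 replicate 3, mock replicate 1 or mock replicate 2. Adjusted over the list alone 4 fell and 1 rose, and camera gave 0.0152, or adjusted p = 0.54 with an estimated correlation.

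Cytokinin genes also moved both ways at 6 h. Of 28 cytokinin response genes 3 rose and 5 fell, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.0249, toward lower values, and adjusted p = 0.256 with an estimated correlation). UGT85A1 and UGT76C2, which glucosylate cytokinins, rose (1.17 ± 0.18 and 0.77 ± 0.14), and LBD3 fell (−1.58 ± 0.23). The response regulator ARR5, a common reporter of cytokinin signalling, had a log2 fold change of −0.34 ± 0.20 with an adjusted p of 0.328. In a fit of the 6 libraries of this time with the replicate number as a block, chosen after the data were seen, ARR5 stood at −0.31 with an adjusted p of 0.0429 (0.0429–0.75 over the alternatives run). Of 29 genes of cytokinin metabolism and signalling 6 rose and 2 fell, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.491). LOG1, which releases active cytokinin (AT2G28305, chromosome 2, 12081023–12084678), rose (1.38 ± 0.24), while IPT3 and IPT7, which make its precursors, fell (−0.81 ± 0.15 and −1.40 ± 0.26).

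Of 15 cell expansion genes 10 fell and 0 rose at 6 h, both over all genes and adjusted over the list alone (camera adjusted p = 1.67e-10, 0.0108 with an estimated correlation), among them XTH19 (−1.31 ± 0.18) and EXPA10 (−1.31 ± 0.16). Of 10 sulfur assimilation genes 6 fell and 0 rose under either adjustment (camera adjusted p = 1.67e-06, 0.0354 with an estimated correlation), including APR1, an adenosine phosphosulfate reductase (−1.21 ± 0.19). Of 14 ethylene genes 3 rose, or 6 adjusted over the list alone, and 0 fell (camera adjusted p = 0.000993, 0.0186 with an estimated correlation), with EBF2 at 0.76 ± 0.13 and EIN3 at 0.46 ± 0.12. Of 14 root hair genes 7 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.000184, adjusted p = 0.256 with an estimated correlation). Of 17 abscisic acid and drought genes 5 fell, or 6 adjusted over the list alone, and 0 rose, CYP707A1 and HAI1 among them (−1.07 ± 0.16 and −1.30 ± 0.25, camera adjusted p = 0.0007, adjusted p = 0.149 with an estimated correlation).

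Of the nitrogen list, 4 of 21 genes rose and 0 fell at 6 h under either adjustment. These included HRS1, a repressor of the phosphate response (0.88 ± 0.11), BT2 (1.93 ± 0.38) and TGA1, a regulator of the nitrate response (0.58 ± 0.14). The nitrate transporter NRT2.1 stood at −0.08 ± 0.32 (adjusted p = 0.908) and the list did not pass camera (0.725). Of 38 cell division genes 1 rose, the G1 cyclin CYCD1;1 (1.14 ± 0.14, adjusted p = 1.46e-05), and 1 fell, CYCD3;1 (−0.62 ± 0.18, 0.0247). The adjusted p of CYCD3;1 was 0.0592–0.126 without AtCEP5 replicate 2, mock replicate 1 or mock replicate 3. Adjusted over the list alone the counts were the same, and camera gave 0.789. Of 20 root meristem genes 1 passed over all genes and 0 adjusted over the list alone. It was JKD, a zinc finger gene of ground tissue patterning, at 0.61 ± 0.19 (adjusted p = 0.0424, 0.0746–0.169 without any 1 of the AtCEP5 libraries or of mock replicates 1 and 2). The circadian clock list had 1 of 12 genes higher and 4 lower, or 2 and 4 adjusted over the list alone, with a camera adjusted p of 0.0808, of 0.045 with the replicate number as a block, and of up to 0.486 over the alternatives run.

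In edgeR's test 2247 of 19938 genes changed at 6 h, 1185 higher and 1062 lower with AtCEP5, and 768 of them by at least 1 on the log2 scale. Limma on the deposited FPKM values, which differs from edgeR's test in scaling, model and filter at once, called 1531 genes higher and 792 lower. The count was 1329 without AtCEP5 replicate 2, 1234 without AtCEP5 replicate 3 and 1426 without mock replicate 1, and the blocked fit of the 6 libraries of this time called 4802 genes (2344 higher, 2458 lower).

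After 12 h MIOX4 rose by 5.80 ± 0.53, ASN1 by 5.72 ± 0.62, from 1.03 ± 0.644 to 53.7 ± 12.1 CPM, and SEN1 by 5.56 ± 0.65 (log2 ± SE, n = 3 against 3). GAT1_2.1 rose by 4.99 ± 0.61, the dark-inducible oxygenase gene DIN11 by 3.77 ± 0.77 and BCAT-2 by 3.66 ± 0.42. NRT1.8, which takes nitrate out of the xylem sap (AT4G21680, chromosome 4, 11517353–11519805), rose by 3.83 ± 0.27 with an adjusted p of 6.10e-09. TPS13 had 89 reads with AtCEP5 and 2 with mock, a ratio of 48.7 after scaling for depth, with a counting interval of 13.1–408. ATC (−6.25 ± 0.33, adjusted p = 1.09e-10), the glutamate decarboxylase GAD3 (−4.16 ± 0.68) and the glucosyltransferase UGT84A1 (−3.36 ± 0.33) fell. SCPL32 (−3.28 ± 0.65), SWEET14 (−3.03 ± 0.58), TFL1 itself (−2.75 ± 0.36) and PIL1, a light-regulated basic helix-loop-helix gene (−2.64 ± 0.50), fell too. BBX30 (−2.70 ± 0.86, adjusted p = 0.0414) stood at −1.37 (adjusted p = 0.405) without mock 12 h replicate 1, and did not pass without any 1 of the AtCEP5 libraries (0.073–0.146).

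CEP5 was lower with AtCEP5 at 12 h, at 0.713 ± 0.399 against 8.63 ± 1.07 CPM (log2 −3.601 ± 0.359, adjusted p = 7.55e-07), and CEP4 had 1 read against 125, a ratio of 114 after scaling for depth, with a counting interval of 20.13–4548 (from 13.1 without AtCEP5 replicate 1, and at least 13.05-fold lower without replicate 2). CEPH, a phosphatase gene of nitrate uptake, rose (1.40 ± 0.33), so that 1 of the 6 tested CEP pathway genes was higher and 2 were lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.253). CEPD1 (0.65 ± 0.28, adjusted p = 0.14), CEPR1 (0.18 ± 0.21, 0.646) and CEPR2 (−0.26 ± 0.23, 0.518) did not pass. Without AtCEP5 12 h replicate 3, CEPR2 stood at −0.62 with an adjusted p of 0.0481.

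Of the 40 auxin response genes 1 rose and 3 fell at 12 h, with the same counts adjusted over the list alone (camera adjusted p = 0.35). IAA14 fell by 1.39 ± 0.18 and IAA19 by 0.74 ± 0.19 (adjusted p = 0.0105, 0.0562–0.0626 without AtCEP5 replicate 2, AtCEP5 replicate 3 or mock replicate 1). IAA2 rose by 0.54 ± 0.14 (adjusted p = 0.00987, 0.103 without AtCEP5 replicate 1 and 0.0642 without mock replicate 1). Of the 33 auxin transport, synthesis and perception genes 9 fell and 0 rose, or 12 and 0 adjusted over the list alone. These included the efflux carrier PIN4 (−1.07 ± 0.15), the influx carrier LAX2 (−0.82 ± 0.14) and the synthesis gene YUC6 (−0.59 ± 0.11). Camera gave 0.000347 for that list, or adjusted p = 0.714 with an estimated correlation.

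Of the 28 cytokinin response genes 2 rose and 5 fell at 12 h, or 2 and 8 adjusted over the list alone, with UGT85A1 and UGT76C2 higher (1.05 ± 0.17 and 0.64 ± 0.14) and LBD3 lower (−1.29 ± 0.23). The list had a camera adjusted p of 0.0531, and of 0.048–0.694 over the alternatives run, the lowest with DESeq2's size factors. ARR5 stood at −0.24 ± 0.20 (adjusted p = 0.511). Among 29 cytokinin metabolism and signalling genes 4 rose and 4 fell, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.843, median 0.03, mean −0.04). LOG1 rose by 1.87 ± 0.25, and IPT3 and IPT7 stood lower at −1.37 ± 0.16 and −1.58 ± 0.26.

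Cell expansion genes were lower in 8 of 15 cases at 12 h, 9 adjusted over the list alone, and higher in 0 (camera adjusted p = 1.48e-07, 0.0245 with an estimated correlation). Sulfur genes were lower in 8 of 10 cases, 9 adjusted over the list alone, and higher in 0 (4.49e-08, 0.0245 with an estimated correlation). Of 9 ribosome biogenesis genes 1 fell, or 7 adjusted over the list alone, and 0 rose (camera adjusted p = 0.00742, adjusted p = 0.714 with an estimated correlation). The nitrogen list had 4 of 21 genes higher and 4 lower, or 6 and 6 adjusted over the list alone. BT2 (2.56 ± 0.39), HRS1 (0.54 ± 0.11) and the xylem loading transporter NRT1.5 (0.86 ± 0.20) were higher and NRT2.1 stood at −0.16 ± 0.33 (adjusted p = 0.813, with 0.884 in camera for the list). In the cell division list 1 of 38 genes rose and 2 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.121), with CYCD1;1 at 0.70 ± 0.14 and CYCD3;1 at −0.94 ± 0.18. CYCA1;1 passed only narrowly (−0.46 ± 0.15, adjusted p = 0.046), and had 0.0678–0.208 without any 1 of the 6 libraries. In the root meristem list 2 of 20 rose under either adjustment. UPB1 stood at 0.83 ± 0.22 (adjusted p = 0.0168, and 0.0519–0.102 without AtCEP5 replicate 1, mock replicate 1 or mock replicate 2). JKD stood at 0.60 ± 0.19 (adjusted p = 0.041, and 0.0661–0.131 without AtCEP5 replicate 2 or 3 or mock replicate 1 or 3). Photosynthesis genes, which mark shoot tissue, had a median of 0.64 at this time, and 1 of 13 rose (2 adjusted over the list alone, camera adjusted p = 0.00698, adjusted p = 0.752 with an estimated correlation).

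In edgeR's test 2417 genes changed at 12 h, 1338 higher and 1079 lower, and 891 by at least 1 on the log2 scale. The count was 1443 without AtCEP5 replicate 1 and 1566 without mock replicate 3.

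After 24 h the raised genes included DIN11 at 4.34 ± 0.79, MIOX4 at 4.07 ± 0.43, SEN1 at 3.76 ± 0.53, BCAT-2 at 3.52 ± 0.41 and ASN1 at 3.51 ± 0.50 (log2 ± SE, n = 3 against 3). ASN1 reached 58.7 ± 1.92 CPM against 5.14 ± 1.94 CPM. SWEET12 (4.05 ± 0.85) and MYB27 (2.82 ± 0.51) rose too. The peptide gene CLE3 passed at 2.94 ± 0.75 (adjusted p = 0.0155), but not without AtCEP5 24 h replicate 1 (0.187) or mock 24 h replicate 2 (0.0808), nor in a fit of the 6 libraries alone (0.0704). ATC fell by 5.68 ± 0.34 (adjusted p = 8.88e-10) and UGT84A1 by 4.01 ± 0.37. SWEET14 (−3.91 ± 0.61), SCPL32 (−3.10 ± 0.63), SULTR1;3 (−3.01 ± 0.53), the early light-induced gene ELIP1 (−2.88 ± 0.34) and TH7 (−2.63 ± 0.34) were also lower. ERF13 (−2.64 ± 0.63) did not pass without mock 24 h replicate 2 (adjusted p = 0.143) or in a fit of the 6 libraries (0.074).

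CEP5 stood at 0.571 ± 0.275 CPM with AtCEP5 and 9.12 ± 2.46 CPM with mock at 24 h (log2 −3.96 ± 0.37, adjusted p = 7.97e-07), and CEP4 had 0 reads against 81, which is at least 8.501-fold lower. CEPD1 passed (0.94 ± 0.28, adjusted p = 0.0425), but had adjusted p values of 0.293 without AtCEP5 replicate 3, 0.0881 without mock replicate 2, 0.169 without mock replicate 3 and 0.154 in a fit of the 6 libraries. CEPR1 (0.29 ± 0.21, 0.496) and CEPR2 (−0.12 ± 0.23, 0.86) did not pass. In all, 1 of the 6 list members rose and 2 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.289, median 0.09, mean −0.857 with CEP4 at its bound).

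Of 40 auxin response genes 2 rose and 4 fell at 24 h under either adjustment, with IAA14 (−1.18 ± 0.18) and IAA19 (−0.87 ± 0.19, adjusted p = 0.0039) lower and GH3.2 higher (1.01 ± 0.17), and camera gave 0.565. Of 33 auxin transport, synthesis and perception genes 1 rose and 2 fell, or 2 and 7 adjusted over the list alone (camera adjusted p = 0.00408, adjusted p = 0.612 with an estimated correlation). The synthesis genes CYP79B2 (−1.18 ± 0.16) and YUC5 (−1.25 ± 0.23) fell, and the influx carrier LAX1 stood at 0.59 ± 0.17 (adjusted p = 0.0313, and 0.0959–0.133 without AtCEP5 replicate 1 or 2 or mock replicate 1 or 2).

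Of 28 cytokinin response genes 1 rose, UGT85A1 (0.92 ± 0.17), and 2 fell at 24 h, with the same counts adjusted over the list alone (camera adjusted p = 0.594). Among those that fell, CKX7, a cytokinin oxidase, stood at −0.96 ± 0.27 (adjusted p = 0.027, and 0.0523–0.125 without AtCEP5 replicate 2 or 3 or mock replicate 2 or 3). LBD3 stood at −0.69 ± 0.21 (adjusted p = 0.0435, and 0.114–0.25 without AtCEP5 replicate 1 or 2 or mock replicate 1). ARR5 was at −0.08 ± 0.20 (adjusted p = 0.888). Among 29 cytokinin metabolism and signalling genes 2 rose and 3 fell, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.505), with LOG1 at 1.72 ± 0.25, IPT7 at −1.98 ± 0.27 and IPT3 at −0.85 ± 0.16.

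Sulfur genes fell in 8 of 10 cases at 24 h and rose in 0 under either adjustment (camera adjusted p = 6.77e-11, 0.0119 with an estimated correlation). Cell expansion genes fell in 6 of 15 cases and rose in 0 under either adjustment (3.21e-05, and adjusted p = 0.103 with an estimated correlation). Of 11 suberin genes 4 fell, or 8 adjusted over the list alone, and 0 rose, among them CYP86B1 (−1.25 ± 0.25), the transporter ABCG6 (−1.20 ± 0.22) and the feruloyl transferase ASFT (−0.90 ± 0.16). Camera gave 1.99e-06 for suberin, or adjusted p = 0.292 with an estimated correlation. The nitrogen list had 2 of 21 genes higher and 2 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.846, median 0.01, mean −0.03). NRT1.5 rose (1.21 ± 0.20). HRS1 stood at 0.39 ± 0.11 (adjusted p = 0.0367, and 0.0704–0.175 without any 1 of the AtCEP5 libraries or of mock replicates 2 and 3). NRT1.1, a nitrate transporter and sensor, stood at −0.93 ± 0.26 (adjusted p = 0.0302, and 0.0523–0.198 without any 1 of the AtCEP5 libraries or of mock replicates 1 and 2). NRT2.1 was at −0.45 ± 0.33 (adjusted p = 0.513). In the cell division list, CYCD1;1 stood at 0.43 ± 0.14 (adjusted p = 0.0673) and CYCD3;1 at −0.34 ± 0.17 (0.279), and camera gave 0.649. Of 20 root meristem genes 3 rose under either adjustment, UPB1 (0.97 ± 0.23), WOX5 (0.82 ± 0.24) and T5L1 (0.43 ± 0.13). The adjusted p of UPB1 was 0.0623 without AtCEP5 replicate 3 and 0.0738 without mock replicate 2, that of WOX5 0.0873–0.184 without AtCEP5 replicate 2 or 3 or mock replicate 2 or 3, and that of T5L1 0.0536–0.147 without any 1 of the 6 libraries. Camera gave 0.296 for the list.

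In edgeR's test 1558 genes changed at 24 h, 737 higher and 821 lower, and 589 by at least 1 on the log2 scale. The count was 980 without AtCEP5 replicate 1, 1003 without AtCEP5 replicate 2, 1032 without mock replicate 1, and 897 in a fit of the 6 libraries of this time.

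Averaged over the 3 times (9 AtCEP5 and 9 mock libraries), ATC was 1.49 ± 1.08 CPM with AtCEP5 and 68.9 ± 22.7 CPM with mock, with a log2 fold change of −5.68 ± 0.18 and an adjusted p of 2.95e-15. MIOX4 rose by 5.47 ± 0.31 (adjusted p = 2.62e-11). Raised genes also included ASN1 (4.73 ± 0.34), TPS13 (4.33 ± 0.38), DIN11 (4.31 ± 0.50), GAT1_2.1 (3.83 ± 0.34), BCAT-2 (3.602 ± 0.261), SWEET12 (3.27 ± 0.41) and MYB27 (2.84 ± 0.27). Lowered genes included SWEET14 (−3.63 ± 0.34), SULTR1;3 (−3.61 ± 0.31), UGT84A1 (−3.37 ± 0.20), ELIP1 (−2.68 ± 0.19), the galactinol synthase GolS3 (−2.50 ± 0.20), TFL1 (−2.40 ± 0.21) and TH7 (−2.36 ± 0.19). In the CEP pathway list 2 of 6 genes rose, CEPH (0.86 ± 0.18) and CEPD1 (0.69 ± 0.16, adjusted p = 0.00194), and 2 fell, CEP5 (−3.90 ± 0.20) and CEP4 (4 reads against 349), under either adjustment. Camera gave 0.362 (adjusted p), with a median of 0.04 and a mean of −1.22 with CEP4 at its bound at 24 h. CEPR1 (0.24 ± 0.12, adjusted p = 0.14) and CEPR2 (−0.17 ± 0.13, 0.366) did not pass with all libraries. CEPR1 passed without AtCEP5 24 h replicate 3 (0.31, adjusted p = 0.0418) and CEPR2 without AtCEP5 12 h replicate 3 (−0.29, adjusted p = 0.0487). CEP1, CEP2 and CEPD2 had 0 reads in the 21 libraries.

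Of 40 auxin response genes 5 rose and 12 fell in the average under either adjustment, while the list did not pass camera (adjusted p = 0.332). IAA14 (−1.26 ± 0.10, adjusted p = 4.04e-09) and IAA19 (−0.73 ± 0.11, 1.79e-05) fell and GH3.2 rose (0.90 ± 0.10). Of 33 auxin transport, synthesis and perception genes 15 fell, among them CYP79B2 (−0.94 ± 0.09), PIN4 (−0.69 ± 0.09) and YUC6 (−0.40 ± 0.06), and 2 rose, under either adjustment (camera adjusted p = 0.000886, adjusted p = 0.426 with an estimated correlation). Of 28 cytokinin response genes 4 rose and 11 fell, or 4 and 12 adjusted over the list alone, with a camera adjusted p of 0.0519. UGT85A1 (1.05 ± 0.10, AT1G22400, chromosome 1, 7903660–7906969) and UGT76C2 (0.59 ± 0.08) rose. LBD3 (−1.19 ± 0.13, AT1G16530, chromosome 1, 5651268–5652883) and the response regulators ARR15 (−1.26 ± 0.30), ARR17 (−1.61 ± 0.39) and ARR3 (−0.62 ± 0.14) fell, and ARR5 stood at −0.22 ± 0.12 (adjusted p = 0.168). Of 29 cytokinin metabolism and signalling genes 10 rose and 5 fell under either adjustment (camera adjusted p = 0.541). LOG1 (1.66 ± 0.14), LOG5 (2.51 ± 0.43) and the response regulator ARR11 (0.90 ± 0.12) rose. IPT3 (−1.01 ± 0.09, AT3G63110, chromosome 3, 23317971–23319636), IPT7 (−1.65 ± 0.15) and LOG2 (−1.59 ± 0.26) fell.

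**Figure D2:**
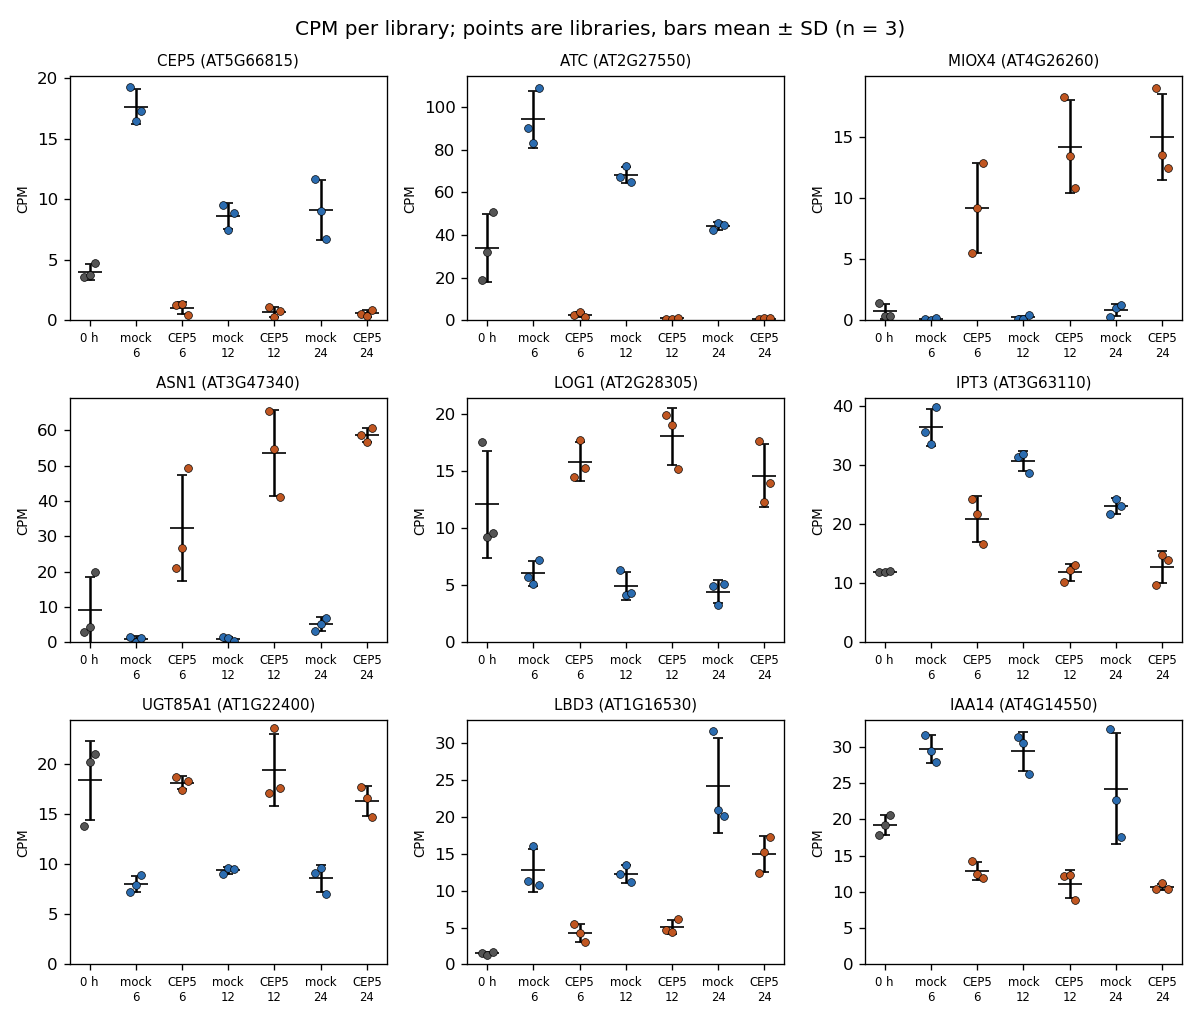
CPM (y axis) of 9 genes in each library (points), with the group mean and SD (bars, n = 3), in the order before treatment (0 h), then mock and AtCEP5 at 6, 12 and 24 h on the x axis. CEP5 stands at 0.998, 0.713 and 0.571 CPM in the AtCEP5 groups and at 8.63 and 9.12 CPM in the mock groups at 12 and 24 h, and ASN1, MIOX4, LOG1 and UGT85A1 are higher and ATC, IPT3, IAA14 and LBD3 lower with AtCEP5.

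Cell expansion and sulfur lists passed camera in the average with either correlation. Of 15 cell expansion genes 10 fell and 0 rose under either adjustment (adjusted p = 2.61e-08, 0.0168 with an estimated correlation), including the xyloglucan endotransglucosylases XTH19 (−1.47 ± 0.11), XTH17 (−1.19 ± 0.10) and the expansin EXPA10 (−1.01 ± 0.09). Of 10 sulfur genes 9 fell, or 10 adjusted over the list alone, and 0 rose (1.16e-08, 0.0168 with an estimated correlation), including LSU2 (−2.31 ± 0.17), SDI1 (−1.87 ± 0.22) and APR1 (−1.46 ± 0.11). Of 14 root hair genes 9 fell, or 11 adjusted over the list alone, and 0 rose, with RHS18 (−0.88 ± 0.12) and EXPA18 (−0.86 ± 0.11) among them (camera adjusted p = 0.000423, adjusted p = 0.396 with an estimated correlation). Of 11 suberin genes 6 fell, or 7 adjusted over the list alone, and 0 rose, such as CYP86B1 (−0.87 ± 0.14) and ASFT (−0.65 ± 0.09), with 0.00273 in camera and adjusted p = 0.426 with an estimated correlation. Of 9 ribosome biogenesis genes 7 fell, or 8 adjusted over the list alone, and 0 rose, such as the fibrillarin FIB2 (−0.58 ± 0.09), with 0.00273 in camera and adjusted p = 0.445 with an estimated correlation. Of 13 jasmonate genes 5 fell, or 6 adjusted over the list alone, and 0 rose, JAZ1 (−0.85 ± 0.08) and VSP1 (−1.17 ± 0.19) among them (0.0337, adjusted p = 0.396 with an estimated correlation).

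Further lists did not pass camera in the average. Of 21 nitrogen genes 4 rose, or 5 adjusted over the list alone, and 8 fell (0.787). NRT1.5 (0.95 ± 0.11), BT2 (1.90 ± 0.22) and HRS1 (0.60 ± 0.07) rose, the nitrate reductase NIA1 fell (−1.08 ± 0.26) and NRT2.1 was at −0.23 ± 0.19 (adjusted p = 0.389). Of 38 cell division genes 2 rose and 6 fell (0.541), with CYCD1;1 (0.76 ± 0.08) higher and CYCD3;1 (−0.63 ± 0.10) and PCNA1 (−0.42 ± 0.10) lower. Of 15 cell cycle inhibitors 2 rose, including KRP4 (0.55 ± 0.08), and 3 fell, including KRP7 (−0.67 ± 0.16), with 0.677 in camera. Of 20 root meristem genes 4 rose, including UPB1 (0.80 ± 0.13) and JKD (0.46 ± 0.11), and 1 fell, MGP (−0.36 ± 0.09). Camera gave it 0.945 with the direction up, while the median was −0.09 and the mean −0.05. Of 12 clock genes 2 rose, including RVE1 (0.76 ± 0.11), and 3 fell, including GI (−1.86 ± 0.12, adjusted p = 1.45e-10), with 0.376 in camera. Of 14 ethylene genes 6 rose and 1 fell (0.0808), and of 17 abscisic acid and drought genes 2 rose and 7 fell (0.0519). In the lists of this paragraph other than nitrogen the counts adjusted over the list alone were the same.

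**Figure D3:**
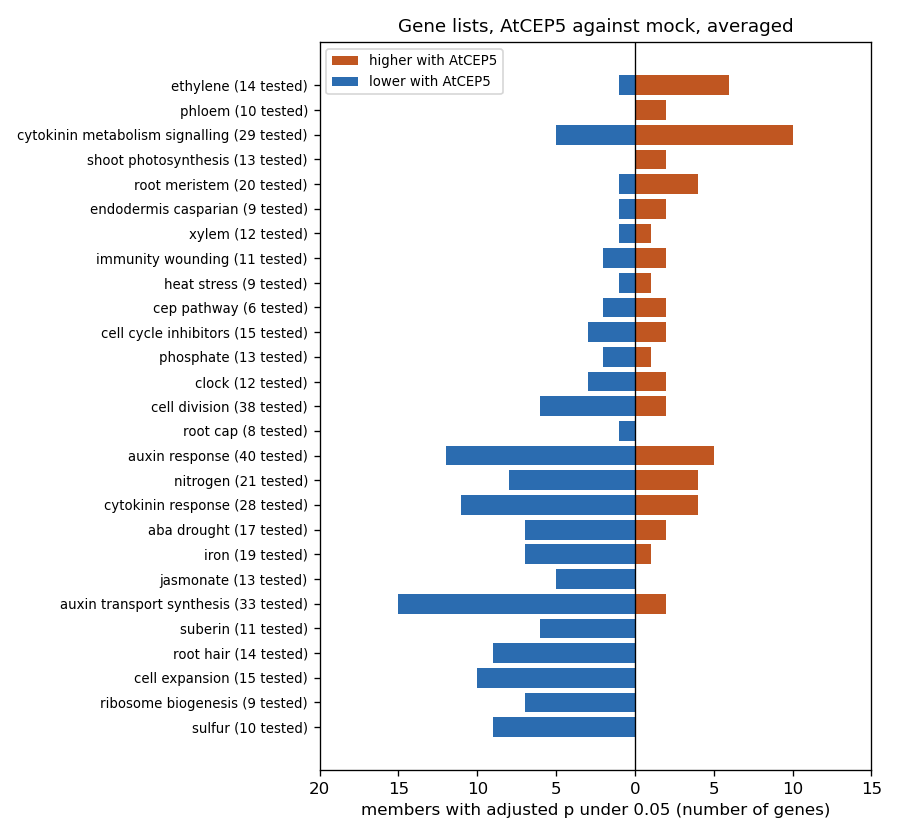
Number of members of each of the 27 gene lists with an adjusted p under 0.05 (x axis) for AtCEP5 against mock averaged over 6, 12 and 24 h, drawn to the right for genes higher with AtCEP5 and to the left for genes lower, with the number of genes tested beside each list name on the y axis. The sulfur (9 of 10) and cell expansion (10 of 15) lists hold lower genes alone, and the cytokinin metabolism and signalling list has the most higher genes (10 of 29).

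In the average 6032 genes passed edgeR's test, 2951 higher and 3081 lower, and 839 of them by at least 1 on the log2 scale. The 3 times, which share no libraries, overlapped in their calls: 806 genes were higher at both 6 and 12 h where independent lists would share 79.5, 541 at 6 and 24 h (43.8) and 591 at 12 and 24 h (49.5). For lower genes the overlaps were 610 (57.5), 468 (43.7) and 502 (44.4). No gene was called in opposite directions at any pair of times (count 0), and 499 genes were higher and 386 lower at all 3 times, of 3589 called at 1 time or more.

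Few genes differed in their AtCEP5 effect between times when the difference itself was tested. In edgeR 1 gene passed for 12 h against 6 h, OSM34, 2 for 24 h against 6 h, OSM34 and the peroxidase gene Prx37, and 3 for 24 h against 12 h, NRT1.8, Prx37 and the ethylene response factor gene ORA59. OSM34, an osmotin-like gene, stood at 0.38 ± 0.17 at 6 h (adjusted p = 0.173) and rose by 2.55 ± 0.18 at 12 h and 2.42 ± 0.18 at 24 h. At unadjusted p under 0.05 in edgeR the 3 differences had 756, 818 and 802 of 19938 genes. Each is below the share of 0.05 that chance alone would give. DESeq2 called 9, 16 and 7. For 24 h against 12 h the count was 1 without AtCEP5 24 h replicate 2 or 3, mock 12 h replicate 1 or 3 or mock 24 h replicate 1. It was 5 without AtCEP5 24 h replicate 1 and 7 without AtCEP5 12 h replicate 3. For 24 h against 6 h it was 5 without AtCEP5 24 h replicate 1 or mock 6 h replicate 3.

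The comparison of mock with the libraries taken before treatment gives the change with time and handling without the peptide. The nitrate transporter NRT2.1 went from 3.26 ± 1.67 CPM before treatment to 478 ± 53.8 CPM at 6 h (log2 7.20 ± 0.45, n = 3 each). SULTR1;3 rose by 5.03 ± 0.53, and CWINV5 and CYP710A3, both at 0 reads before treatment, were at least 21.5-fold and 11.7-fold higher. Genes that rose at 12 h included the iron acquisition genes CYP82C4 (6.99 ± 0.49), FRO2 (4.87 ± 0.33) and IRT1 (4.64 ± 0.41) and NRT2.1 (4.81 ± 0.41). At 24 h they included CYP82C4 (5.09 ± 0.47), the expansin EXPB2 (at least 17.1-fold), CWINV5 (at least 13.3-fold) and SCPL32 (82 reads against 2, interval 10.5–328, from 6.65 without the second library taken before treatment). Among lowered genes, the sugar exporter SWEET12 stood at −7.17 ± 0.56, −7.18 ± 0.55 and −9.08 ± 0.65 at 6, 12 and 24 h and SWEET11 at −7.97 ± 0.41 at 24 h. SWEET3 went from 429 reads to 2 at 6 h (interval 49.7–1497 for the ratio, from 32.5 without mock replicate 3), 1 at 12 h (78.6–17436, from 51.0 without mock replicate 3, and at least 48.3-fold lower without replicate 2) and 0 at 24 h (at least 48.9-fold lower). Other lowered genes were GSTF3 (at least 9.92-fold) and LHCB2.2 (at least 23.5-fold, from 5.79 ± 8.82 CPM, a spread larger than its mean) at 6 h. Both bounds rested on the third library taken before treatment, without which they were 5.25-fold for GSTF3 and 2.80-fold for LHCB2.2. Others were the stress-related transcription factor genes DDF1 (at least 33.3-fold) and RRTF1 (1 read against 219, interval 39.9–8920, from 25.9 without mock replicate 3, and at least 24.7-fold lower without replicate 1) at 12 h, and CCOAMT (1 against 99, 18.1996–4140) at 24 h. The CCOAMT interval began at 7.14 without the third library taken before treatment and at 11.7 without mock replicate 2, and without mock replicate 3 the gene was at least 11.5-fold lower.

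Of 19 iron genes 15 rose and 3 fell in mock at 6 h (camera adjusted p = 4.59e-07, adjusted p = 0.0894 with an estimated correlation), and 13 rose and 1 fell at 12 h (3.40e-07, 0.0418 with an estimated correlation). Of 21 nitrogen genes 14 rose and 2 fell (7.47e-06, adjusted p = 0.133 with an estimated correlation). Of 9 ribosome biogenesis genes 9 rose, FIB2 by 1.59 ± 0.16 (3.05e-07, adjusted p = 0.134 with an estimated correlation), and the counts of these 3 lists were the same adjusted over the list alone. Cell division genes rose in 21 and fell in 3 of 38 cases, or 22 and 3 adjusted over the list alone (0.000292, adjusted p = 0.308 with an estimated correlation). Cell expansion genes rose in 8 and fell in 0 of 15, or 9 and 0 adjusted over the list alone (7.56e-05, adjusted p = 0.0953 with an estimated correlation). In the CEP pathway list 4 of 6 genes rose, CEPH (5.74 ± 0.46), CEPD1 (3.67 ± 0.36), CEP5 (2.14 ± 0.28) and CEP4 (1.19 ± 0.38), under either adjustment. Camera gave 0.00133, and adjusted p = 0.0953 with an estimated correlation. Abscisic acid and drought genes fell in 12 of 17 cases at 6 h and in 15 (16 adjusted over the list alone) at 12 h, with NCED3 at −2.94 ± 0.23 at 12 h. Camera gave 0.000189 and 3.63e-08, and adjusted p = 0.103 and 0.034 with an estimated correlation. Photosynthesis genes fell in 10 of 13 cases (12 adjusted over the list alone) at 6 h (0.000511, adjusted p = 0.392 with an estimated correlation). The third library taken before treatment had 16.0 CPM of LHCB2.2, against 0.563 and 0.826 in the first and second, and the list was not tested without it.

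Auxin response genes were lower in mock than before treatment in 15, 12 and 8 of 40 cases at 6, 12 and 24 h and higher in 3, 3 and 0. Adjusted over the list alone 15, 12 and 5 were lower and 3, 3 and 0 higher. Camera gave 0.0397, 0.0174 and 0.0419, or adjusted p = 0.308, 0.255 and 0.265 with an estimated correlation. Of 28 cytokinin response genes 6 rose and 9 fell at 6 h, or 6 and 10 adjusted over the list alone (camera adjusted p = 0.893, median −0.18, mean 0.06), with ARR5 lower (−1.30 ± 0.20).

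In mock against before treatment the clock gene CCA1 stood at −1.91 ± 0.30 at 6 h, −2.86 ± 0.32 at 12 h and −0.88 ± 0.28 at 24 h, the last with an adjusted p of 0.0202 that became 0.191 without the third library taken before treatment and 0.0909 without mock 24 h replicate 3. LHY stood at −1.66 ± 0.34, −2.38 ± 0.35 and −0.57 ± 0.33 (adjusted p = 0.182 at 24 h), and PRR7 at −1.71 ± 0.23, −2.08 ± 0.23 and −1.40 ± 0.22. GI, an evening gene, rose at 6 h (0.94 ± 0.20). PRR9, PRR5, ELF3 and ELF4 did not pass at any of the 3 times with all libraries. ELF4 passed at 6 h (0.87, adjusted p = 0.00577) and at 12 h (0.63, 0.0436) without the first library taken before treatment, and at 24 h (−0.87, 0.0166) without the third. PRR5 and ELF3 passed at 24 h without mock replicate 1 (−0.57, 0.018) and mock replicate 2 (−0.49, 0.00978). Of 12 clock genes 2 rose and 6 fell at 6 and at 12 h and 0 rose and 5 fell at 24 h, under either adjustment. Camera gave 0.107, 0.0346 and 0.0419, or, at 12 and 24 h, adjusted p = 0.262 and 0.256 with an estimated correlation.

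In edgeR's test 7724 genes differed between mock at 6 h and the libraries taken before treatment (3628 higher, 4096 lower), 7455 at 12 h (3537 and 3918) and 6996 at 24 h (3307 and 3689). For 24 h a fit of the 6 libraries alone called 4285. AtCEP5 at 6, 12 and 24 h differed from the libraries taken before treatment in 5527 (2607 higher, 2920 lower), 4718 (2087 and 2631) and 5583 (2561 and 3022) genes, and in 2909 at 12 h in a fit of the 6 libraries alone. The comparisons with the libraries taken before treatment share those 3 libraries.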

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

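No test in this part was chosen after its result was seen. The 4 genes below were singled out because their AtCEP5 effect differed between times in a test of the difference itself. OSM34, an osmotin-like gene, had a larger effect at 12 h than at 6 h by 2.17 ± 0.25 (log2 ± SE, adjusted p = 0.000222) and at 24 h than at 6 h by 2.04 ± 0.24 (0.000281). It stood at 43.6 ± 3.05, 212 ± 30.5 and 431 ± 73.1 CPM with AtCEP5 and 33.5 ± 5.04, 36.2 ± 3.79 and 80.6 ± 17.37 CPM with mock at 6, 12 and 24 h (mean ± SD, 3 libraries each). Prx37, a peroxidase gene, rose with AtCEP5 at 6 h (1.90 ± 0.13) and 12 h (adjusted p = 1.26e-05) and stood at −0.17 ± 0.13 at 24 h (adjusted p = 0.516). Its difference between 24 and 6 h was −2.08 ± 0.18 (1.95e-06), and that between 24 and 12 h −1.17 ± 0.18 (0.0145, and 0.0524–0.0844 without AtCEP5 24 h replicate 2 or 3, mock 12 h replicate 1 or 3 or mock 24 h replicate 1).

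NRT1.8, which takes nitrate out of the xylem sap, had effects of 1.79 ± 0.28, 3.83 ± 0.27 and 0.55 ± 0.27 at 6, 12 and 24 h, and its difference between 24 and 12 h was −3.27 ± 0.38 (adjusted p = 0.000375). ORA59, an ethylene response factor gene of jasmonate and ethylene responses, had effects of 2.17 ± 0.23, 2.35 ± 0.23 and 0.40 ± 0.23, and its difference between 24 and 12 h was −1.95 ± 0.33 (0.0361). The ORA59 difference had adjusted p values of 0.067–0.234 without AtCEP5 12 h replicate 1 or 2, AtCEP5 24 h replicate 2 or 3, any 1 of the mock 12 h libraries or mock 24 h replicate 1 or 2. It also did not pass with a replicate block (0.0841), in limma on log2(FPKM + 0.1) (0.0692) or in limma with any FPKM above 0 (0.103).

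Chance was not excluded for the number of genes whose effect differed between times. Of 21 splits of the libraries, the real one included, 2 gave as many genes for 12 h against 6 h (1 gene, highest other split 2), 3 for 24 h against 6 h (2 genes, highest other 11) and 4 for 24 h against 12 h (3 genes, highest other 24). The times were shuffled separately within AtCEP5 and within mock. Uneven splits therefore carry the change with time into the difference, and mixed groups widen the spread. For these reasons the splits cannot decide whether chance gave these numbers.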

How the results depend on the processing

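Leaving out both libraries with a ribosomal RNA share over 1% and fitting the 6 libraries of 6 h alone with a replicate block were chosen after the data were seen. No scaling moved the median of all genes by over 0.1, and none of the 72 passing list tests changed the sign of its median with RLE or FPKM scaling (count 0 each). Of the values of named genes, 235 of 238 kept direction and call with RLE, 236 of 237 with DESeq2, 231 of 238 with the replicate block, 211 of 216 with limma on log2(FPKM + 1) and 227 of 238 without both libraries high in ribosomal RNA. Requiring an absolute log2 fold change of at least 1, which by construction lowers every count, left 768, 891, 589 and 839 genes for AtCEP5 against mock at 6, 12 and 24 h and in the average, 2714, 2486 and 2208 for mock against before treatment, and 1808, 1653 and 1879 for AtCEP5 against before treatment. With it the overlaps between times held 309 higher and 183 lower genes for 6 and 12 h, 208 and 144 for 6 and 24 h, and 244 and 152 for 12 and 24 h. Fitting the 6 libraries alone called 897 genes for AtCEP5 against mock at 24 h, 4285 for mock at 24 h and 2909 for AtCEP5 at 12 h against before treatment, and 4802 for AtCEP5 against mock at 6 h with a replicate block. The cause was not tested. Without both libraries high in ribosomal RNA the AtCEP5 against mock counts were 1631, 2447, 1505 and 5759. With 1 library left out in turn they ranged over 1234–1909 at 6 h, 1443–2529 at 12 h and 980–1632 at 24 h, with fewer libraries in each fit, and over 5268–6064 in the average.

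For the difference between 12 and 6 h DESeq2 called 9 genes, limma on log2(FPKM + 1) 4, limma with any FPKM above 0 5, and edgeR without both libraries high in ribosomal RNA 2. For 24 against 6 h edgeR with no filter on low counts called 7, DESeq2 16 and limma on log2(FPKM + 1) 5. For 24 against 12 h edgeR with no filter called 5, DESeq2 7, and edgeR without both libraries high in ribosomal RNA 7. With 1 library left out these counts ranged over 2–5 (24 against 6 h) and 1–7 (24 against 12 h). The cause was not tested. Among lists, the cytokinin response list had an adjusted p of 0.256 with an estimated correlation at 6 h, 0.0487 with a replicate block and 0.048 with RLE at 12 h, and 0.0492 with a replicate block in the average. The auxin response list had 0.308, 0.255 and 0.265 with an estimated correlation for mock at 6, 12 and 24 h against before treatment, where an estimated correlation widens the test by construction.

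Some calls were lost with other settings. CYCA1;1 at 12 h and T5L1 at 24 h did not pass with RLE (adjusted p = 0.0602 and 0.0537), nor LBD3, CEPD1 and HRS1 at 24 h with a replicate block (0.0663, 0.0664 and 0.0521). Some values that did not pass changed sign. With 1 library left out, NRT2.1 ranged over −0.446 to 0.0703 at 6 h and −0.709 to 0.138 at 12 h in AtCEP5 against mock, and ARR5 over −0.267 to 0.0163 and CEPR2 over −0.264 to 0.0465 at 24 h. The range was −0.773 to 0.184 for PRR9, mock at 6 h against before treatment, and −0.825 to 0.149 for PRR9, mock at 24 h against before treatment. In the same comparisons ELF4 ranged over −0.0888 to 0.869 at 6 h, −0.332 to 0.626 at 12 h and −0.872 to 0.086 at 24 h, and PRR5 over −0.052 to 0.207 at 12 h. NRT2.1 in AtCEP5 against mock at 6 h was 0.00871 without both libraries high in ribosomal RNA. ELF4 in mock at 12 h was 0.00132 with no filter on low counts, 0.0467 with a replicate block, and 0.177, 0.178 and 0.177 in limma on log2(FPKM + 1), on log2(FPKM + 0.1) and with any FPKM above 0. The cause was not tested. Depth limits genes near 0 reads, such as CEP4, whose fold has wide counting intervals.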

Other observations

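Of 10 phloem genes 2 rose averaged over the 3 times (AtCEP5 against mock, log2 ± SE, 9 libraries each), the sucrose transporter SUC2 (1.64 ± 0.17) and PP2-A1 (0.34 ± 0.09), and 0 fell (camera adjusted p = 0.203). Of 12 xylem genes 1 rose, ACL5, a thermospermine synthase (0.92 ± 0.08), and 1 fell, or 1 and 0 adjusted over the list alone (0.585). Of 9 endodermis genes 2 rose, the Casparian strip gene CASP5 (1.17 ± 0.16) and its regulator MYB36 (0.43 ± 0.11), and 1 fell (0.843, median −0.13, mean 0.14). Of 8 root cap genes 1 fell, BRN1 (−0.72 ± 0.14), and 0 rose (0.843). Of 19 iron genes 1 rose, BHLH101 (0.98 ± 0.21), and 7 fell, including BHLH39 (−0.84 ± 0.14) and OPT3 (−0.60 ± 0.12), with 0.0497 in camera, 0.0502 with RLE and adjusted p = 0.426 with an estimated correlation. Of 13 phosphate genes 1 rose, PHO1 (0.56 ± 0.10), and 2 fell, including PHT1;4 (−0.79 ± 0.13), with 0.576 in camera. Unless stated, counts adjusted over the list alone were the same.

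Of 9 heat genes 1 rose, HSFA7A (1.64 ± 0.17), and 1 fell (0.541), with the same counts adjusted over the list alone. Of 11 immunity and wounding genes 2 rose, including MYB51 (0.72 ± 0.17), and 2 fell, including WRKY11 (−0.41 ± 0.08), under either adjustment. Camera gave 0.945, and its direction was up while the median was −0.02 and the mean −0.12. Of 13 photosynthesis genes 2 rose, or 1 adjusted over the list alone, GAPA (0.44 ± 0.12) and PSBO1 (0.39 ± 0.15), and 0 fell (0.208).

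The tests of reads from shoot tissue and of sequencing depth were chosen after the result was seen, and the other tests before, although both patterns below were found in these data. Genes induced by low sugar were higher with AtCEP5. A list of 17 such genes, written after the genes with the largest changes were seen and leaving those out, had a median log2 fold change of 1.26 in the average (16 rose, among them TPS8, DIN10 and IVD, and EXL1 fell, adjusted p = 0.0116 with an estimated correlation). A shared low-sugar response may account for this rise. That test could have come out the other way, but the list was prompted by genes seen to rise in these same libraries. It is therefore not independent support. Reads from shoot tissue as the whole cause were argued against by the photosynthesis list. Its medians at 6, 12 and 24 h were 0.253, 0.645 and −0.0534 (SD over members 0.574, 0.36 and 0.416), where the low-sugar list had 1.31, 1.28 and 1.17. At 12 h the photosynthesis list rose as well (camera adjusted p = 0.00698, adjusted p = 0.752 with an estimated correlation), so a part from shoot tissue stays open there. For sequencing depth, the log2 ratios of mean total counts, AtCEP5 against mock, were 0.15, −0.117 and −0.208 at 6, 12 and 24 h. Each was smaller in size than the low-sugar median minus its SD over members (0.454, 0.348 and 0.334). The fold changes were already scaled for library size, so this comparison shows only that the groups were of similar depth. It cannot decide whether depth played a part. Sugar was not measured, so lower sugar in these roots is not established. The list was compared with mock only, and its change since before treatment was not tested. Among the genes left out of it, SEN1, BCAT-2 and ATCTH at 6 h lay below their level before treatment in both groups, and lower in mock. ASN1, MIOX4 and GAT1_2.1 with AtCEP5 lay above that level. A fall in mock that was smaller with AtCEP5 therefore stays open for the list.

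The AtCEP5 effect ran opposite to the change of mock since before treatment. The effect at 1 time was correlated with the mock change at another, which share no library, across 19938 genes, which are not independent replicates. The 6 Pearson correlations ranged from −0.457 to −0.307 (Spearman −0.482 to −0.316), which argues against noise in shared mock libraries as the whole cause. Expression common to the mock groups of different times would still enter both values with opposite signs and give a negative correlation. The 500 genes that fell most in mock had median AtCEP5 effects of 0.399–1.01. At 24 h these were 0.399 and 0.722, and the photosynthesis median of −0.0534 (SD 0.416) argues against reads from shoot tissue as the whole cause. At 6 and 12 h the photosynthesis medians of 0.253 (SD 0.574) and 0.645 (SD 0.36) do not argue against it, where the genes that fell most had 0.46 and 0.504 at 6 h and 1.01 and 0.808 at 12 h, so reads from shoot tissue stay open at these times. At 24 h AtCEP5 may keep part of the root transcriptome nearer to its state before treatment, a hypothesis that was found and tested on the same libraries. The correlations cannot decide it, since what the mock groups have in common gives the same sign. On PC1 AtCEP5 at 24 h (mean −10.1) lay nearer to the libraries taken before treatment (−47.7) than mock at 24 h did (18.1). On PC2 it lay farther from them (25.5 with AtCEP5, −5.06 with mock and −31.7 before treatment).

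For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split, 1 of 10 in each case, gave 2247, 2417 and 1558 genes for AtCEP5 against mock at 6, 12 and 24 h, where the highest other split gave 0, 0 and 6. It gave 7724, 7455 and 6996 for mock against before treatment (highest other 0, 0 and 1) and 5527, 4718 and 5583 for AtCEP5 against before treatment (0, 12 and 0). For the average, 1 of 31 splits, the real one, gave as many as 6032 genes, and the highest other gave 16, a share under 0.05. Splits that mix the groups put the difference between them into the spread, which lowers their calls. The replicates may also be technical, so the splits cannot exclude a chance difference between cultures.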
